A study of Homo sapiens with 8 samples.

How the data were processed

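The series measured poly(A) RNA in U937 cells, a human monocytic line, in which SLC19A1 had been knocked out. SLC19A1 is the reduced folate carrier and also imports cyclic dinucleotides such as cGAMP. A doxycycline-inducible, Flag-tagged SLC7A1 or SLC7A2 had been introduced into these cells, which gave 2 lines. SLC7A1 and SLC7A2 encode cationic amino acid transporters, which carry arginine and lysine. Each line was studied without doxycycline and after 24 h in 1 µg/mL doxycycline, with 2 libraries in each of the 4 groups, 8 libraries in all. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures. The p-value of a gene therefore measures only the spread between these samples, which may be technical. Per the labels, RNA had a RIN above 7, 200 ng entered each library, and paired reads of 150 bases were made from DNA nanoballs.

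Each deposited file holds 1 library. The authors gave for every gene an expected count, which per the file headers comes from RSEM and need not be whole. The deposited FPKM, which relates fragments to effective gene length and depth, and the gene lengths per the file headers were not used in any test. The deposited TPM sums to the same total over the listed genes of each library and was used for levels and for 1 alternative. The submitters' processing notes name HISAT, Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the build hg38, with no role or order. The use of strand in counting is not given in the sources used here, so overlapping and antisense genes are uncertain. The files list only genes with a count above 0, and a gene missing from a file was taken as 0. Over the 8 libraries 22653 entries were listed: 15386 Entrez gene numbers, 7264 assembled loci with XLOC identifiers and 3 added entries for the constructs. Of the Entrez numbers 15340 matched a symbol in the reference table. The XLOC loci held 6.56% to 7.25% of the counts of a library. They have no symbol here and are named only where a count rests on them.

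Total expected counts ran from 17309132 to 18441833 per library, so 3 counts, used as the floor, were 0.163 to 0.173 CPM (the count scaled to the total of the library). Floors cover counting error only, since reads carry no molecular identifiers. Replicates of a group differed by far more than sampling noise, with a chi-square per gene of 20.66 to 45.63, so no file was taken as a library deposited a second time. This does not test whether libraries of a group came from 1 culture.

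Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17503 entries, of which 11567 had a symbol and 5927, or 33.9%, were XLOC loci. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Of the 6 comparisons, 5 used 1 fit of the 4 group means over all 8 libraries: dox in the SLC7A1 line, dox in the SLC7A2 line, the difference between these effects, and the lines set against each other without and with dox. The sixth, dox across both lines, used an additive fit of line and dox with 4 libraries in each arm. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The p-values were adjusted over the lists of a comparison, with camera on an estimated correlation and fry beside it. With the preset correlation camera sets the members of a list against all other genes. Its p-value then rests on the spread across genes and not on that between samples. An estimated correlation rests on only 4 or 5 residual degrees of freedom without a block. How often camera then finds a real shift was not simulated. The log2 fold changes are fitted values, and for an entry near 0 in 1 group they depend on the fit and are no bound. The SE beside an edgeR value was derived from its F statistic, as the absolute log2 fold change over the square root of F. For an entry near 0 in 1 group this SE does not give the uncertainty of the fold change. The SE beside a DESeq2 value is the one DESeq2 gives. CPM values of single genes in the comparisons are TMM-normalised, and those of the transporters are scaled to the library total alone.

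The gene lists, the design, the alternatives and the rule for named genes were set before the data were examined, except where an addition is named. Of 33 lists 31 had members to test. The list of mitochondrially encoded mRNAs had 0 of 13 members in the files, and the erythroid and megakaryocyte list had 3 of 12 in the files and 0 past the filter. The lists contain neither SLC7A1 nor SLC7A2. Named genes were to be SLC7A1, SLC7A2 and SLC19A1, the genes with the highest and lowest fold changes among those under an adjusted p of 0.05 with a mean log2 CPM of at least 1 and arms that did not overlap, and for each list the called members or, with none called, up to 2 members with the highest mean CPM. No gene passed in edgeR. HLA-B, B2M, STING1, IRF3, FDPS, RPS18, ENO1, HSPA8, TFRC, COL1A1 and COL3A1 were among the 2 members of their list with the highest mean CPM. The other named genes, and which of these members to give, were chosen after their values were seen.

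Same-numbered samples were checked for shared deviations from their group means. Over all tested genes the correlation was 0.197 in the SLC7A1 line and 0.312 in the SLC7A2 line. Between the lines it ran from -0.024 to 0.15. Over the 4933 symbol genes with a mean log2 CPM of at least 5 it was 0.703 and 0.771 within the lines and 0.038 to 0.445 between them. The numbers were taken to pair samples within a line, which makes 4 pairs but only 2 independent correlations. A weaker structure by number that the lines share was also pointed to. Among the splits of the libraries given below, that of numbers 1 against numbers 2 had the most edgeR calls, 599. The replicate block planned beforehand shared a number between the lines. The block within a line was added after seeing the data.

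Alternatives planned beforehand were RLE size factors, no filter and a stricter filter (CPM of at least 1 in at least 2 libraries), the Wald test of DESeq2 1.42.0, the shared replicate block, each library left out in turn, a minimum log2 fold change of 1, only the 4 libraries compared, and TPM for the correlation of effects. Those chosen after seeing the data were the block within a line in edgeR and DESeq2, the addition of a locus with identical counts to the SLC7A1 transgene entry, the omission of both SLC7A2-line libraries numbered 2, symbol genes only, and leaving out each library for the lists.

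The tests were tested on simulated counts with known changes for 17503 genes. For dox in the SLC7A1 line, edgeR recovered 11% of 2-fold and 60% of 4-fold changes, with 6 false among 77 calls. The additive fit recovered 40% and 75%, with 5 false among 120 calls. With the block within a line it recovered 37% and 74%, with 14 false among 125 calls. Camera gave a list of 20 genes shifted by 0.3 on the log2 scale an adjusted p of 0.0132 and called 0 of 30 unshifted lists. The simulated genes varied independently of each other, and the simulated libraries held no effect shared by a pair. The simulation therefore does not show how camera treats lists of correlated genes. Nor does it show how the fits with or without the block treat paired samples. The recovered shares may therefore not hold for the real libraries. There the SLC7A1 construct itself had an edgeR adjusted p of 0.138 in its line without a block. Tables and figures were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.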

Results

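Gene expression was measured in U937 SLC19A1 knockout cells that carried a doxycycline-inducible SLC7A1 or SLC7A2, with and without 24 h of doxycycline. Each of the 4 groups held 2 libraries, with 17309132 to 18441833 expected counts in each. The series title concerns SLC7A1 and the response of T cells to cGAMP through STING, and these lines address what raising either transporter does to the transcripts of a monocytic cell. There was no line without a construct that received doxycycline, so a response shared by both lines cannot be divided between the drug and the transporters.

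The induced constructs were read first. The entry for Flag-tagged SLC7A1 had 845 and 367 CPM in the SLC7A1 line with dox, against 0.264 and 0 CPM without, and 0 in all 4 libraries of the SLC7A2 line. The entry for Flag-tagged SLC7A2 had 264 and 4947 CPM in the SLC7A2 line with dox, against 0.563 and 9.65 CPM without. In the SLC7A1 line it had 1 count in 1 library and 0 in the others. The short Flag entry had 2.54 and 1.85 CPM in the SLC7A1 line with dox and 0.578 and 11.2 CPM in the SLC7A2 line with dox. The locus XLOC_024383 had counts identical to those of the SLC7A1 construct entry. Whether both hold the same sequence was not tested, so the values of this construct are those of its entry alone. In edgeR the adjusted p was 0.138 for the SLC7A1 construct in its line (log2 fold change 12.01 ± 0.84 SE) and 1 for SLC7A2_Flag (8.93 ± 1.80), a value that ran from 5.71 without the dox library numbered 2 to 12.06 without the no-dox library numbered 2. With the replicate block within a line, which takes the difference between same-numbered samples, both passed at adjusted p values of 0.0109 and 0.00216.

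The endogenous SLC7A1 gene (Entrez 6541, chromosome 13, 29509414 to 29595688 in GRCh38.p14) had 73.2 ± 0.045 CPM without and 113 ± 27.4 CPM with dox in the SLC7A1 line (SD, n = 2). In the SLC7A2 line it had 68.1 ± 12.2 and 82.8 ± 24.4 CPM (SD, n = 2). The log2 fold changes were 0.62 ± 0.23 and 0.24 ± 0.23 (SE), neither past the edgeR test (adjusted p = 1). It was higher with dox in each of the 4 same-numbered pairs, and DESeq2 with the replicate block within a line called it in the SLC7A1 line (0.60 ± 0.13, adjusted p 0.00289) and across both lines (0.42 ± 0.11, adjusted p 0.0242), while edgeR with that block did not (1 and 0.832). In the SLC7A1 line this gene may share reads with the construct, so its level there is uncertain. In the SLC7A2 line its value was -0.04 without the dox library numbered 2. Endogenous SLC7A2 (Entrez 6542, chromosome 8, 17494069 to 17570566) had 1 count in 1 library and 0 in the other 7. SLC19A1 (Entrez 6573, chromosome 21, 45502517 to 45563025), the knocked-out gene, still gave group means of 127 to 149 CPM. A gene can keep its mRNA after a disrupting edit, and with no wild type in the series these counts do not check the knockout.

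**Figure D1:**
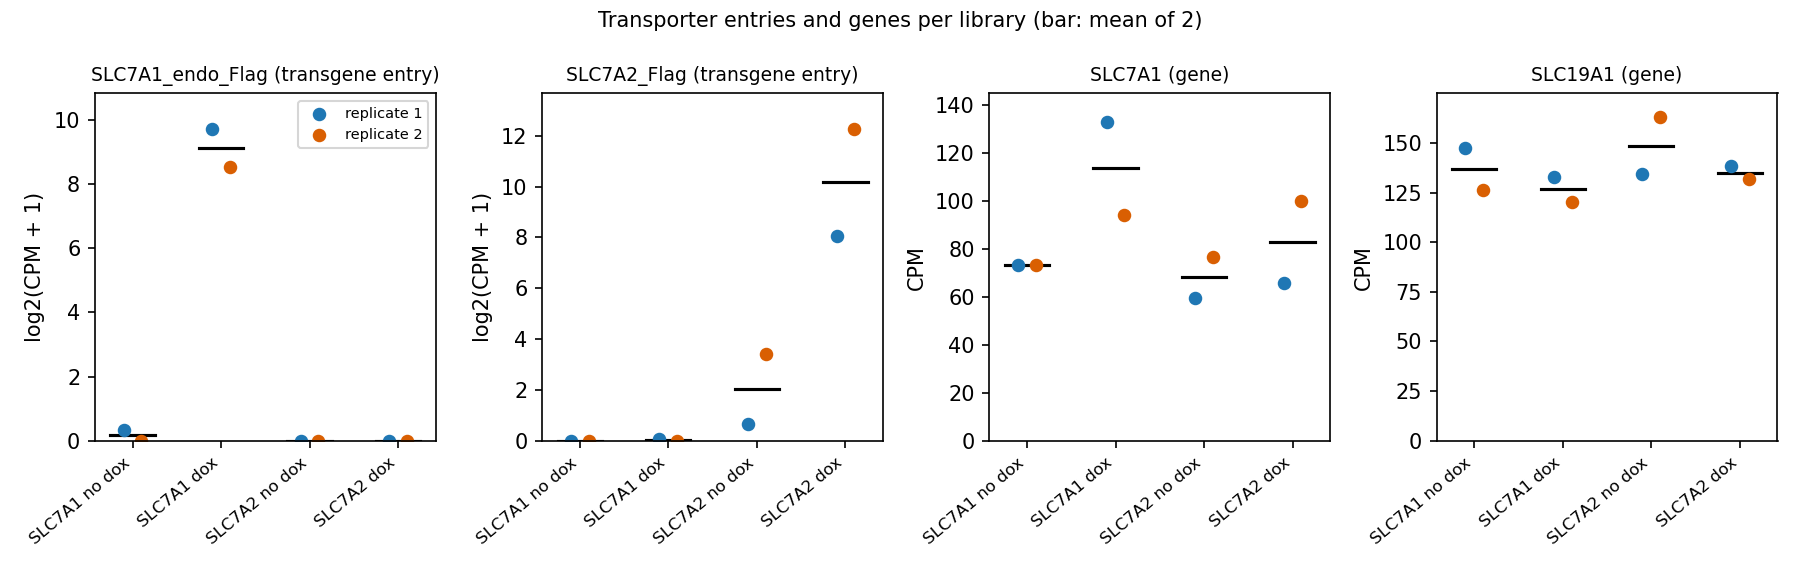
Levels of both construct entries as log2(CPM + 1) and of the SLC7A1 and SLC19A1 genes as CPM, in each of 8 libraries (points, coloured by replicate number, with a bar for the mean of 2). The construct entries are high with dox in their own line, from 264 to 4947 CPM, and SLC19A1 group means lie between 127 and 149 CPM.

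Dox in the SLC7A1 line asked which transcripts follow induction of SLC7A1. Genes of the ATF4 response, which supplies amino acids and charged tRNA when amino acids run short, lay higher with dox, with all 23 measured members above 0 and a median log2 fold change of 0.21. PSAT1, an enzyme of serine synthesis, had 174.5 ± 12.7 CPM without and 225 ± 58.8 CPM with dox (SD, n = 2). NRF2 targets of the oxidative stress response were higher in 16 of 17 members, with a median of 0.20. PGD of the pentose phosphate pathway had a value of 0.26 ± 0.18 (SE). Genes of cholesterol synthesis were lower in 22 of 22 members, with a median of -0.27, among them INSIG1, a sterol-regulated gene, at -0.59 ± 0.40. Glycolysis and hypoxia genes were lower in 23 of 28 members, with a median of -0.18, and NDRG1 had -0.53 ± 0.44.

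These 4 lists passed camera at adjusted p values of 0.0246 for ATF4, 0.0408 for NRF2, 0.00041 for cholesterol and 0.0281 for glycolysis, and each had an adjusted p = 0.870 with an estimated correlation. No member passed adjusted over the list alone. Over all genes edgeR called 0 of 17503, with 222 at an unadjusted p under 0.05 where 875 were expected by chance. With the replicate block within a line 744 lay under 0.05, so the shortfall depends on how the pairs are treated. It is no evidence that no gene responded. DESeq2 called 9 genes, 5 higher and 4 lower, of which 6 were XLOC loci. With the replicate block within a line edgeR called 2 (SLC7A1_endo_Flag and XLOC_024383), DESeq2 45 (18 higher, 27 lower, with INSIG1 at an adjusted p of 1.31e-05) and camera 10 lists. The 6 lists added by the block were cGAMP sensing (0.0271, higher), amino acid transporters (0.0313, higher), NFkB genes (0.0377, higher), myeloid granule genes (0.00939, lower), metallothioneins (0.0271, lower) and the unfolded protein response (0.0271, lower). With an estimated correlation under this block the adjusted p = 0.710 for granule genes and 0.692 for the other 5. Single omissions used no block and left 1 sample without its same-numbered partner, so they partly mix dox with replicate number. The medians of both same-numbered pairs of this line were 0.27 and 0.15 for ATF4 and -0.35 and -0.21 for cholesterol. For glycolysis they were -0.26 and -0.07. Without the SLC7A1 dox library numbered 1 the ATF4, cholesterol and glycolysis lists turned direction, at adjusted p values of 0.469, 0.944 and 0.644. Over single omissions INSIG1 ran from -1.24 to -0.01, the latter without the no-dox library numbered 2, and NDRG1 and PSAT1 came to -0.09 and 0.07 without the dox library numbered 1. The ATF4 list also turned without the no-dox library numbered 2 (0.843), where cholesterol had 0.576, glycolysis 0.788 and NRF2 0.0955. Without the no-dox library numbered 1 and the dox library numbered 2 the NRF2 list had 0.397 and 0.347, and without either SLC7A2-line dox library glycolysis had 0.0545 and 0.0544.

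Dox in the SLC7A2 line asked the same of SLC7A2. ATF4 genes were again higher in 23 of 23 members, with a median of 0.22, and PSAT1 had 163 ± 14.0 CPM without and 244 ± 73.5 CPM with dox (SD, n = 2). Interferon-stimulated genes were higher in 24 of 31 members, with a median of 0.27. OAS3, a sensor of double-stranded RNA, had 0.35 ± 0.19 (SE) and PARP9 0.67 ± 0.28. Ribosomal protein genes were lower in 40 of 41 members, with a median of -0.11, OXPHOS subunits in 34 of 38 with -0.07, granule genes such as RNASE2 (-0.28 ± 0.19) in 14 of 16 with -0.17, and glycolysis genes in 25 of 28 with -0.13.

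Collagen transcripts set 1 library of this comparison apart. COL1A1 had 24.5 CPM in the no-dox library numbered 2 and at most 4.90 CPM in each of the other 7. The fibroblast marker list was accordingly lower with dox, with a median of -2.90 over 4 members, and COL1A1, COL1A2 and COL3A1 passed adjusted over the list alone at 0.0142, 0.0260 and 0.0142, with log2 fold changes of -2.78, -3.02 and -3.46. Without the no-dox library numbered 2 these were -1.20, -0.63 and -1.17. The other no-dox library had the next highest COL1A1 level, and without the library numbered 2 the list still passed (0.0219), but it did not pass with an estimated correlation (adjusted p = 0.976).

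Camera gave adjusted p values of 0.00366 for ATF4, 0.000381 for interferon and for fibroblast genes, 0.00331 for ribosomal proteins, 0.00471 for granule genes, 0.0119 for OXPHOS and 0.0186 for glycolysis, each with adjusted p = 0.976 with an estimated correlation. EdgeR called 0 genes, with 224 at an unadjusted p under 0.05, or 619 with the replicate block within a line. DESeq2 called 10, 8 higher and 2 lower, of which 8 were XLOC loci. With the replicate block within a line edgeR called 1 (SLC7A2_Flag) and DESeq2 26 (14 higher, 12 lower), among them PSAT1 (adjusted p 0.0385, with an edgeR log2 fold change of 0.24 without the dox library numbered 2) and COL1A1 (0.000573). Both SLC7A2-line libraries numbered 2 lay apart on the first principal component, at 37.5 without and 46.9 with dox against -35.3 to -5.7 for the other 6, and without both, an omission chosen after seeing the data, 2 lists passed. Without the dox library numbered 2 the ribosomal list (0.173) and the granule list (0.612) turned direction, and OXPHOS (0.986), glycolysis (0.303), ATF4 (0.192) and interferon genes (0.110) did not pass. Without the no-dox library numbered 2 ATF4 and interferon genes had 0.156. Without the no-dox library numbered 1 ribosomal and glycolysis genes had 0.945 and granule and OXPHOS genes 0.412, and without the dox library numbered 1 glycolysis had 0.135 and fibroblast genes 0.0527.

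The difference between the dox effects set the response of one line against that of the other, free of a drug effect common to both lines. Each transporter was in 1 line only. The transporter therefore cannot be told apart from other differences between the lines, a drug effect particular to a line or the amount of construct. OXPHOS subunits had a lower dox effect in the SLC7A2 line in 36 of 38 members, with a median difference of -0.13. The OXPHOS medians of the same-numbered pairs, with dox minus without, were -0.07 and 0.16 in the SLC7A1 line and -0.05 and -0.11 in the SLC7A2 line, so the pairs numbered 1 did not show this difference. NDUFA1 had 60.2 ± 3.91 and 68.5 ± 6.50 CPM without and with dox in the SLC7A1 line and 67.8 ± 1.22 and 60.6 ± 4.54 CPM in the SLC7A2 line (SD, n = 2). UQCRFS1 had a difference of -0.26 ± 0.17 (SE). Fibroblast markers had a median difference of -2.67, with COL1A1 at -2.89 ± 1.04, or -1.30 without the SLC7A2 no-dox library numbered 2, and both SLC7A2-line no-dox libraries had the highest COL1A1 levels of the 8.

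Both lists had a camera adjusted p of 0.00882 and adjusted p = 0.977 with an estimated correlation. EdgeR called 0 genes with 222 at an unadjusted p under 0.05, or 519 with the replicate block within a line. DESeq2 called 20 (13 higher, 7 lower), of which 17 were XLOC loci. With the replicate block within a line DESeq2 called 21, and camera added NFkB genes (0.0103), NRF2 targets (0.0493) and cholesterol synthesis (0.0103, higher), each with adjusted p = 0.961 with an estimated correlation under this block. Without both SLC7A2-line libraries numbered 2, 0 lists passed. Leaving out 1 library ended the OXPHOS call for the SLC7A1 no-dox number 2 (0.160), SLC7A1 dox number 2 (0.598), SLC7A2 no-dox number 1 (0.174) and SLC7A2 dox number 2 (0.622), and the fibroblast call for SLC7A1 no-dox number 2 (0.0894), SLC7A1 dox number 1 (0.0516), SLC7A2 dox number 1 (0.0986) and SLC7A2 dox number 2 (0.0594). Over 17503 genes the effects of dox in the lines had a Pearson correlation of 0.004 and a Spearman correlation of 0.082, and over the 4933 symbol genes with a mean log2 CPM of at least 5 these were 0.301 and 0.262. Genes are not independent replicates, and edgeR without a block called no gene in either line, so no overlap of its calls was counted. DESeq2 called genes in each line, and with the replicate block within a line some in both, but that overlap was not tested.

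Dox across both lines pooled the response. ATF4 genes were higher in 23 of 23 members, with a median of 0.20, among them PSAT1 at 0.47 ± 0.17 and JDP2 at 0.39 ± 0.13 (SE). Their median was above 0 in each of the 4 same-numbered pairs. Cytosolic tRNA synthetases, which charge tRNA with amino acids, were higher in 14 of 20 members, with a median of 0.08, including MARS1 at 0.32 ± 0.11, GARS1 at 0.26 ± 0.09, AARS1 at 0.25 ± 0.14 and WARS1 at 0.20 ± 0.08. Interferon-stimulated genes were higher in 23 of 31 members, with a median of 0.22, with OAS3 at 0.36 ± 0.12 and OAS1, of about 1.52 to 3.34 CPM, at 0.78 ± 0.33. In the SLC7A1 line alone 19 of 31 were higher, with a median of 0.03, and camera did not call them (adjusted p 0.155). Cell division genes of G2 and mitosis were higher in 23 of 26 members, with a median of 0.06.

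Cholesterol synthesis genes were lower in 22 of 22 members, with a median of -0.17, among them FDPS at -0.18 ± 0.11 and INSIG1 at -0.42 ± 0.27. In the SLC7A2 line alone the median of this list was -0.04, and camera did not call it (adjusted p 0.332). Glycolysis and hypoxia genes were lower in 25 of 28, with a median of -0.14, and ENO1 had -0.21 ± 0.13 and NDRG1 -0.51 ± 0.29. Granule genes of myeloid progenitors were lower in 16 of 16, with a median of -0.19, and RNASE2 had -0.22 ± 0.12. Metallothioneins and metal response genes were lower in 8 of 10, with a median of -0.14, and TFRC, the transferrin receptor, had -0.49 ± 0.29. Ribosomal protein genes were lower in 39 of 41, with a median of -0.07, and fibroblast markers had a median of -1.47. The pair medians of the fibroblast markers were 0.34 and 0.02 in the SLC7A1 line and -1.02 and -3.26 in the SLC7A2 line. GLUL, which makes glutamine, had -0.51 ± 0.38, CAT, the catalase gene, -0.32 ± 0.14, and MYC -0.20 ± 0.11.

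Camera gave adjusted p values of 6.48e-05 for ATF4, 0.000296 for interferon, cholesterol and glycolysis genes, 0.000397 for granule genes, 0.00766 for ribosomal proteins, 0.0171 for tRNA synthetases and metallothioneins, 0.0288 for G2 and mitosis and 0.0346 for fibroblast markers. With an estimated correlation the adjusted p = 0.620 for interferon genes and tRNA synthetases, 0.736 for ATF4, cholesterol, glycolysis, granule, metallothionein and fibroblast genes, 0.742 for G2 and mitosis and 0.915 for ribosomal proteins. Across all 6 comparisons 0 of the 45 list calls held with an estimated correlation, and fry called 1, the tRNA synthetases here (adjusted p 0.00462). The estimate rests on 4 or 5 residual degrees of freedom, so a list that fails with it is not shown to be unchanged. No member of these lists passed adjusted over the list alone. EdgeR called 0 genes, with 261 at an unadjusted p under 0.05, or 1020 with the replicate block within a line. DESeq2 called 1 (Flag_Cterm).

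With the replicate block within a line edgeR called 3 entries (SLC7A1_endo_Flag, SLC7A2_Flag and XLOC_024383) and camera 12 lists. The block added cGAMP sensing and transport genes (0.0115, higher in 15 of 17 members), NRF2 targets (0.0098, higher) and the unfolded protein response (0.00971, lower), and fibroblast markers did not pass (0.117). With an estimated correlation under this block the adjusted p = 0.564 for cGAMP genes and the unfolded protein response and 0.595 for NRF2. DESeq2 with this block called 106 genes, 49 higher and 57 lower, including MARS1 (adjusted p 8.54e-09), AARS1 (3.45e-06), GARS1 (1.52e-05), JDP2 (2.22e-05), PSAT1 (0.00228), GLUL (2.15e-08), TFRC (3.38e-07), CAT (1.52e-05) and INSIG1 (0.00155). An exchange of dox and no dox in 1 of the 4 pairs gave 174 such calls and 8 lists. In edgeR over single omissions GLUL ran from -0.79 to -0.24, TFRC from -0.72 to -0.27 and INSIG1 from -0.62 to -0.15. Interferon genes passed camera without any single library, at up to 0.0486, but not with an estimated correlation (adjusted p = 0.620). Without the SLC7A1 no-dox library numbered 2 and the SLC7A1 dox library numbered 1, ATF4 had 0.0739 and 0.144, cholesterol 0.202 and 0.433, glycolysis 0.0739 and 0.147, and metallothioneins 0.110 and 0.310. Granule genes did not pass without the SLC7A2 dox library numbered 2 (0.302), where ribosomal proteins turned direction (0.604). Ribosomal proteins had 0.605 and 0.742 without the no-dox libraries numbered 1 of the SLC7A1 and SLC7A2 lines. The tRNA synthetases had 0.0739 without SLC7A1 no-dox number 2, 0.0520 without SLC7A1 dox number 2, 0.0656 without SLC7A2 no-dox number 2 and 0.156 without SLC7A2 dox number 1. Metallothioneins had 0.167 without SLC7A2 no-dox number 2 and 0.156 without SLC7A2 dox number 1. G2 and mitosis genes had 0.733 without SLC7A1 no-dox number 1, 0.0725 and 0.133 without SLC7A1 dox numbers 1 and 2, 0.143 without SLC7A2 no-dox number 2 and 0.263 without SLC7A2 dox number 2. Fibroblast markers had 0.0639 without SLC7A1 dox number 2, 0.406 without SLC7A2 no-dox number 2, and 0.224 and 0.302 without SLC7A2 dox numbers 1 and 2.

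**Figure D2:**
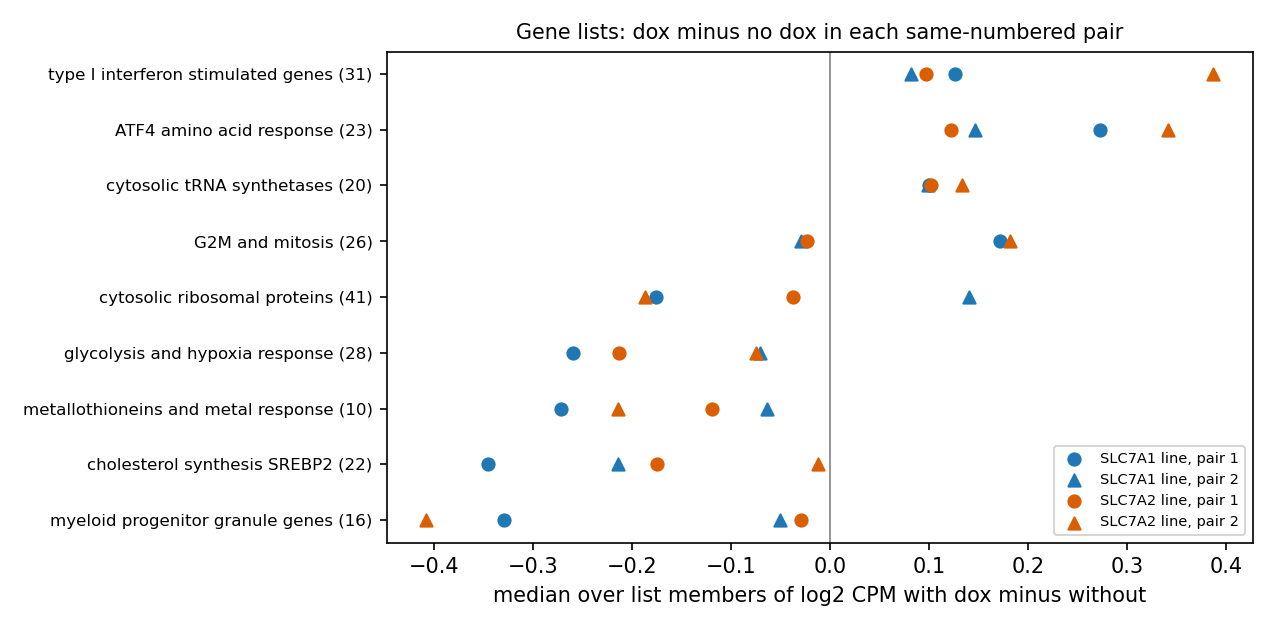
Median over the members of a list of log2 CPM with dox minus without, for each same-numbered pair of the SLC7A1 line (blue) and the SLC7A2 line (orange), for lists called across both lines other than fibroblast markers, with the number of measured members. ATF4 medians lie at 0.27, 0.15, 0.12 and 0.34, and the ribosomal and G2 lists have pairs on both sides of 0.

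The other lists did not pass across both lines without the block. Amino acid transporters were higher in 13 of 17 members (adjusted p 0.159) and mitochondrial ribosomal proteins lower in 21 of 28 (0.165). Adjusted p values were 0.350 for ribosome biogenesis, 0.424 for mitochondrial chaperones and epithelial markers, and 0.489 for OXPHOS subunits, macrophage differentiation and B cell markers. They were 0.616 for lysosome genes and 0.910 for p53 targets. They were 0.979 for immediate early genes, G1/S genes, NFkB genes, antigen presentation, arginine and polyamine metabolism, the folate pathway, heat shock genes and T cell markers. The median was 0 for arginine and polyamine metabolism, with 10 of 20 members above 0.

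The lines without dox were compared as a baseline, with values given as the SLC7A2 line over the SLC7A1 line. Heat shock genes were higher in 15 of 15 members, with a median of 0.80, among them the chaperone HSPA8 with 2065 ± 1100 against 775 ± 354 CPM and HSPB1 with 368 ± 37.5 against 224 ± 33.0 CPM (SD, n = 2). NRF2 targets were higher in 17 of 17, with a median of 0.36, and NQO1, a quinone reductase, had 1.12 ± 0.37 (SE). Ribosomal protein genes were lower in 41 of 41, with a median of -0.33, and RPS18 had -0.48 ± 0.20. Antigen presentation genes were lower in 13 of 16, with a median of -0.48, and HLA-B and B2M of MHC class I had -0.85 ± 0.27 and -0.53 ± 0.18. Cholesterol genes were higher in 17 of 22, unfolded protein response genes in 17 of 20, ribosome biogenesis genes in 23 of 26, mitochondrial ribosomal proteins in 22 of 28 and fibroblast markers in 4 of 4. ATF4 genes were lower in 18 of 23, interferon genes in 23 of 31 and glycolysis genes in 22 of 28.

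Camera adjusted p values were 4.27e-09 for ribosomal proteins, 6.57e-07 for heat shock, 7.08e-05 for NRF2, 0.000397 for antigen presentation, 0.000814 for ribosome biogenesis and fibroblast markers, 0.0135 for the unfolded protein response, 0.0154 for cholesterol and interferon genes, 0.0191 for ATF4 and mitochondrial ribosomal proteins and 0.0405 for glycolysis. The adjusted p = 0.707 to 0.709 with an estimated correlation. Adjusted over the list alone, COL1A1, COL1A2, COL3A1 and ATP13A2, a lysosomal polyamine transporter (0.73), passed. EdgeR called 0 genes, with 931 at an unadjusted p under 0.05, and DESeq2 35 (23 higher, 12 lower), of which 19 were XLOC loci and 2 were COL3A1 (0.00979) and ATP13A2 (0.0115). Without both SLC7A2-line libraries numbered 2, 6 lists passed in place of 12, and without the no-dox one alone HSPA8 and NQO1 had 0.73 and 0.66. Ribosomal proteins, heat shock, NRF2 and fibroblast markers passed camera without any single library, at up to 0.0228, but not with an estimated correlation (adjusted p = 0.707). Without the SLC7A1 no-dox library numbered 1 the other lists except glycolysis had 0.063 to 0.819, and without the SLC7A2 no-dox library numbered 2 the unfolded protein response, ribosome biogenesis, interferon, ATF4, mitochondrial ribosomal and glycolysis lists had 0.0613 to 0.506. ATF4 and cholesterol genes had 0.0849 and 0.2997 without SLC7A2 no-dox number 1, mitochondrial ribosomal and glycolysis genes 0.0969 and 0.642 without SLC7A1 no-dox number 2, and glycolysis 0.0687 and 0.0686 without SLC7A2 dox numbers 1 and 2.

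With dox 5 of the 7 lists higher at baseline passed camera again in the SLC7A2 line over the SLC7A1 line, none of them with an estimated correlation (adjusted p = 0.806). Values were higher for heat shock in 15 of 15, cholesterol in 20 of 22, the unfolded protein response in 18 of 20, ribosome biogenesis in 22 of 26 and NRF2 in 13 of 17 members. HSPB1 had 0.52 ± 0.19, HSPA8 1.20 ± 0.58 and NQO1 0.92 ± 0.37 (SE). Ribosomal proteins were lower in 41 of 41 members, with a median of -0.41 and RPS18 at -0.63 ± 0.20. Antigen presentation genes were lower in 13 of 16 (HLA-B -0.80 ± 0.27, B2M -0.57 ± 0.18), ATF4 genes in 18 of 23, glycolysis genes in 23 of 28 and OXPHOS subunits in 33 of 38.

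Camera adjusted p values were 2.33e-16 for ribosomal proteins, 1.50e-05 for cholesterol, 1.53e-05 for heat shock, 0.000673 for antigen presentation, 0.00117 for the unfolded protein response, 0.0103 for ribosome biogenesis, 0.0163 for OXPHOS, 0.0237 for NRF2, 0.0323 for glycolysis and 0.0402 for ATF4, each with adjusted p = 0.806 with an estimated correlation. No member passed adjusted over the list alone. EdgeR called 0 genes, with 577 at an unadjusted p under 0.05, and DESeq2 24 (14 higher, 10 lower), of which 16 were XLOC loci. Without both SLC7A2-line libraries numbered 2, 6 lists passed in place of 10, and without the dox one alone HSPA8 and NQO1 had 0.64 and 0.41. Ribosomal proteins passed camera without any single library, at up to 1.16e-05, but not with an estimated correlation (adjusted p = 0.806). Without the SLC7A1 dox library numbered 1 the ATF4 list turned direction (0.666), and heat shock, cholesterol, the unfolded protein response, ribosome biogenesis and NRF2 had 0.0539 to 0.762. Without the SLC7A1 dox library numbered 2 glycolysis turned direction (0.818) and OXPHOS had 0.844. Without the SLC7A2 dox library numbered 2 heat shock, the unfolded protein response, antigen presentation, ribosome biogenesis, glycolysis, NRF2 and OXPHOS had 0.0553 to 0.658, and without the SLC7A2 dox library numbered 1 ATF4 had 0.636 and glycolysis 0.123.

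**Figure D3:**
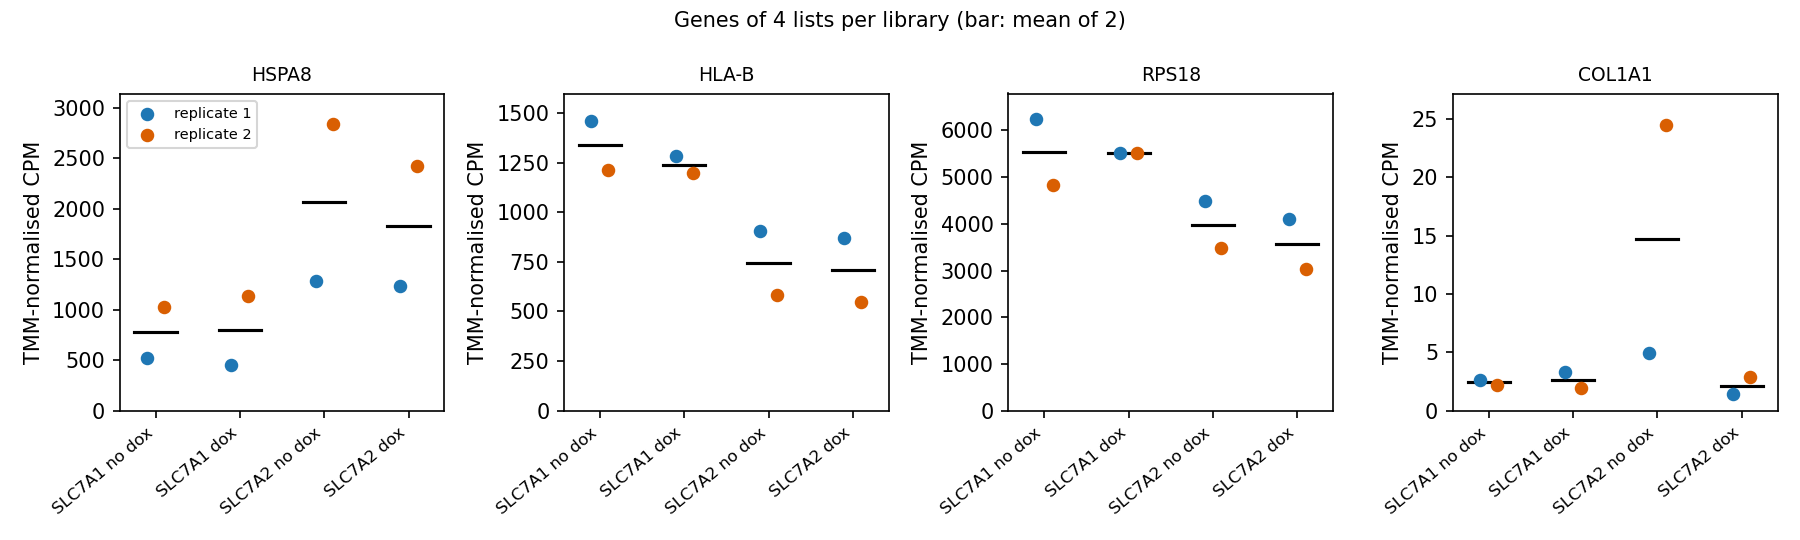
TMM-normalised CPM of HSPA8, HLA-B, RPS18 and COL1A1 in each of 8 libraries (points, coloured by replicate number, with a bar for the mean of 2). HSPA8 was higher and HLA-B and RPS18 were lower in the SLC7A2 line, and COL1A1 reaches 24.5 CPM in 1 library.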

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

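The tests of read crossing, transgene amount, library depth and collagen RNA in the pair of libraries were chosen after the result was seen, and so were the single omissions, while the bounds for other tissues and for further fibroblast genes were written before their values. The dox effect was called different between the lines for OXPHOS subunits and for fibroblast markers, each by a test of the difference itself (camera adjusted p 0.00882, and 0.977 with an estimated correlation). The OXPHOS difference had a median of -0.13 over 38 members and did not pass without any 1 of 4 libraries (0.160 to 0.622). Its pairs numbered 1 did not show it, with medians of -0.07 in the SLC7A1 line and -0.05 in the SLC7A2 line.

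Fibroblast markers were highest in the SLC7A2 no-dox library numbered 2, where COL1A1, COL1A2 and COL3A1 had 24.5, 11.9 and 22.0 CPM, and next highest in its no-dox partner, and the difference still passed without that library (0.0431) but not without any 1 of 4 others (0.0516 to 0.0986). Crossing of reads from another library of the series is argued against, since the highest summed marker level elsewhere was 0.155 of that in this library. RNA of a mixed tissue stays open, since 0 of 6 other tissue lists reached 3 times the next library but 4 of them had 12 to 104 CPM in each library, where a small share would not show. Of 14 further fibroblast genes 6 were highest in this library, where 1.75 were expected and 4 was the upper binomial bound. From these, 2 genes that the earlier list already held were taken out after a first count had included them. The bound takes genes as independent, and the library was picked for its collagen. COL6A2, COL5A1 and COL5A2 were among the 6, at 7.03, 7.64 and 1.71 times the next library. LOX, TIMP3 and SERPINH1, which are no collagens, were also among them, at 5.22, 23.2 and 4.51 times. These 3 had only 1.47, 1.31 and 1.53 CPM there. The count cannot tell fibroblast RNA from another source of these transcripts. RNA of fibroblasts may be a source, and it stays a hypothesis, since BGN, POSTN and COL12A1 had 0 counts there and the design names no such cells.

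Both SLC7A2-line libraries numbered 2 stood apart, with first components of 37.5 and 46.9. The amount of transgene is argued against for the no-dox one, which differed from its no-dox partner 2.75 times as much as the dox library numbered 1 did (2.63 to 2.87 over resampled genes). This compares single libraries and restates their separation on the first component. The interval covers the choice of genes and not the spread between samples. A library with a total between theirs lay at -7.3, but 1 library, of the SLC7A1 line, cannot exclude library depth. RNA of collagen-producing cells is argued against for the pair, since the dox library had a summed marker level of 5.43 CPM, within the range of the other 6. A separate culture or handling day may remain open, since the labels give none.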

How the results depend on the processing

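The blocks within a line, the symbol-only set, the omission of both SLC7A2-line libraries numbered 2 and the single omissions for lists were chosen after seeing the data. RLE size factors, the stricter filter, only the 4 libraries compared and the locus with identical counts added to the SLC7A1 construct left 0 genes called by edgeR wherever run. A minimum log2 fold change of 1 was set on top of the main fit, which already called 0 genes, so it could only leave 0. With no filter edgeR called 2 genes for dox in the SLC7A1 line, 2 across both lines and 2 between the lines with dox, all SLC7A1_endo_Flag and XLOC_024383. DESeq2 called 9, 10, 20, 1, 35 and 24 genes in the order of the comparisons (SLC7A1 line, SLC7A2 line, difference, both lines, lines without dox, lines with dox), and with a replicate block within a line 45, 26, 21 and 106 for the first 4. The replicate block shared by the lines gave 2, 1, 0, 3, 0 and 4 calls in edgeR, the last being SLAMF8, SLC7A1_endo_Flag, SLC7A2_Flag and XLOC_024383, and 45 list calls. The replicate block within a line gave 2, 1, 0 and 3. Symbol genes only gave 1 call for dox in the SLC7A1 line, 1 across both lines and 1 between the lines with dox, each SLC7A1_endo_Flag. Without both libraries numbered 2 of the SLC7A2 line 1 gene (SLC7A2_Flag) was called across both lines and 27 lists passed in place of 45, against 0 with an estimated correlation and 1 by fry.

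The SLC7A1 construct in its line passed at a log2 fold change of 12.02 with no filter and with the shared replicate block, and of 12.01 with the replicate block within a line and with symbol genes only. SLC7A2_Flag passed with a replicate block, at 8.91 shared, 8.93 within a line in edgeR and 8.93 in DESeq2. Over single omissions these folds ran from 11 to 16.43 for the SLC7A1 construct and from 5.71 to 12.06 for SLC7A2_Flag. Leaving out 1 library gave 0 to 1 calls for dox in the SLC7A2 line (XLOC_012691 or CEP350), 0 to 1 between the lines without dox (XLOC_012691) and 0 to 1 with dox (CEP350). CEP350 had 0 CPM in the SLC7A2 dox library numbered 1 alone. The correlation of the dox effects was 0.165 on TPM and -0.054 to 0.032 without 1 library. SLC19A1 was at 0.03 in the SLC7A2 line without its libraries numbered 2 and at -0.25 to 0.02 in the SLC7A1 line without 1 library. Over single omissions SLC7A1 ran from -0.04 to 0.48 and NDRG1 from -0.93 to 0.17 in the SLC7A2 line.

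Adjusted p values of lists that turned direction ran over single omissions from 1.58e-07 to 0.843 (ATF4), 3.34e-09 to 0.944 (cholesterol) and 3.58e-06 to 0.788 (glycolysis) for dox in the SLC7A1 line. They ran from 2.25e-07 to 0.945 (ribosomal) and 1.84e-05 to 0.612 (granule) for dox in the SLC7A2 line, and from 1.72e-06 to 0.742 (ribosomal) across both lines. Between the lines with dox they ran from 8.87e-06 to 0.666 (ATF4) and 2.07e-06 to 0.818 (glycolysis). The replicate block within a line changed no list call beyond those given with the comparisons. Of the values of single genes and lists and the counts of lists per comparison under all alternatives, 1453 kept direction and side of the threshold or stayed within 1.5 times, 204 no longer passed, 17 newly passed, 13 turned direction and 32 counts of lists moved further. No named gene passed in the main fit, so a gene counted as kept wherever its sign held and it still did not pass, however small its value became. The gene counts, the correlation of effects, the total of list calls and the constructs are tallied apart. Of these 138 stayed, 33 moved and 7 newly passed. With 1 library left in a group, that library was assumed to vary like the other groups. Single omissions were fitted without a block, so the same-numbered partner of the omitted library stayed in the fit unpaired. They therefore partly mix the comparison with replicate number. The cause of these changes was not tested beyond the smaller number of samples or genes. Depth limits the SLC7A1 construct entry in its line without dox, with 4.72 and 0 counts against the floor of 3, while SLC7A2_Flag had 10 and 177.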

Other observations

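The tests of the transgene amount, of the edgeR gene count over splits and of the lists over splits that part the pairs were chosen after the result was seen, and the splits of the lists without a block and of the DESeq2 calls before. SLAMF8, a receptor of myeloid cells chosen here after its values were seen, had 12.6 and 54.6 CPM in the SLC7A2 line without dox and 10.8 and 46.3 CPM with dox, against 0.869 to 2.25 CPM in the 4 libraries of the SLC7A1 line. Its log2 fold change between the lines was 4.61 ± 1.01 (SE) without and 4.15 ± 0.99 with dox, at edgeR adjusted p values of 0.855 and 0.926, and it passed with dox under the shared replicate block (0.0439). DESeq2 called it in both comparisons, at 4.64 ± 0.80 (adjusted p 2.42e-05) and 4.16 ± 0.80 (0.00062). STING1, the receptor of cGAMP, had 120 to 155 CPM in the 8 libraries, and IRF3, which acts below it, 94.3 to 125 CPM.

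For the lists called by dox across both lines without a block, 7 of the 34 splits of the 8 libraries into equal arms that could be fitted called at least the real 10, with 12 as the highest other, so chance cannot be excluded in that fit. Most of these splits put both libraries of a same-numbered pair in 1 arm. Of the 8 splits that part all 4 pairs, fitted with the block within a line, 1, the real one, reached its 12 lists, and the highest other called 8. By DESeq2 with that block 2 of the 8 reached the real 106 genes, the other with 174 when the SLC7A1-line pair numbered 2 was exchanged. For both counts 8 splits are too few for a share under 0.05. The 0 genes of edgeR without a block are reached by 34 of 34 splits whatever the data, so that count decides nothing. The highest other split gave 599 genes and sets the libraries numbered 1 against those numbered 2, which points to a structure of the samples by number. On the first principal component the SLC7A1 line was also ordered by number. Its libraries numbered 1 lay at -35.3 and -20.9 and those numbered 2 at -7.3 and -9.2.

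A hypothesis is that the ATF4 list follows the amount of transporter. Its pair medians were 0.27 and 0.15 in the SLC7A1 line, with 840 and 378 TMM-normalised CPM of the construct's own entry, and 0.12 and 0.34 in the SLC7A2 line, with 265 and 4670. The difference between the SLC7A2-line pairs was 0.219, and in both lines the pair with more construct had the larger median. With 1 comparison in each line this cannot be told apart from chance, and with no construct-free line it may be an effect of the drug or of handling.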
